A study of Homo sapiens with 56 samples.

How the data were processed

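RNA of the jejunum was sequenced in 56 libraries from 28 patients, each sampled before and 12 months after Roux-en-Y gastric bypass, and the titles of the samples gave the time, the patient and whether the patient had diabetes. Per the extraction protocol in the labels, messenger RNA was selected with poly-T beads. The protocol describes directional and non-directional libraries without saying which were made, so for genes that overlap another on the opposite strand it is open whose fragments were counted. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to GRCh38 and assigned to genes with featureCounts 1.5.0-p3. Read trimming, the strand setting and the handling of reads that match several genes are not given in the sources used here, so values of near-identical genes such as HBA1 and HBA2, REG1A and REG1B, GSTA1 and GSTA2, HSPA1A and HSPA1B, TPSAB1 and TPSB2 and the metallothioneins are less certain.

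The deposited values are FPKM, that is fragments scaled to gene length and library size, calculated by the authors for 58735 genes, whose IDs, starts and ends were all equal to those of GENCODE release 29. FPKM multiplied by gene length was a whole number of fragments in 100% of the non-zero values (tolerance 0.001), which gave the fragments per gene and library. The scale of each library was its fragments times a factor of 0.735 to 1.18 that the labels do not describe, and the deposited scaling was kept. Libraries held 8.43 to 22.2 M fragments, and 17683 to 28704 genes had a value above 0. The floor of 3 fragments on a gene of 1 kb was 0.128 to 0.403 FPKM. Such floors cover counting error only, since fragments copied by PCR are not independent molecules.

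Genes with a mean of at least 0.5 FPKM over the 56 libraries were tested, without regard to group. Genes of the Y chromosome and XIST, 8 of which passed this filter, were left out before testing, which departs from the written design, and 17293 genes remained, 12900 of them protein-coding. Values were log2(FPKM + 1). The patients' library pairs were checked on sex-linked genes, and 0 of 28 pairs disagreed, which can show only exchanges between patients of different sex. Deviations from the group means were correlated within patients with a median of 0.158 (range -0.104 to 0.540), against -0.00702 between patients, with 17 of 28 above 0.1. Only 13 of 28 baseline and 10 of 28 later libraries correlated best with the other library of their patient, so the pairing was not verified for each patient.

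The tests, filters, gene lists and alternatives were fixed before the data were examined, except those said to be added later. Changes after surgery were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with each patient as a block, in all patients, within each group, and as the difference of the changes between patients with and without diabetes. The groups were also compared at baseline and at 12 months, each within its 28 libraries. The p values were two-sided and adjusted by Benjamini and Hochberg over the tested genes, with a threshold of 0.05. Tables were handled with the data.table package, version 1.17.8. On simulated data with the real library sizes, 200 genes changed by known folds were recovered as the closing section states, and in a simulated list test 0 of 58 unchanged lists were called. Genes were simulated independently of each other, so neither that list test nor the gene counts say anything about false calls from correlated genes. The simulated spread was set from a part of the observed variance, so recovery in the real data may be lower.

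There were 62 gene lists, 32 of functions and 30 of cell types or neighbouring tissues, of which 59 had at least 2 tested genes. Those not tested were the pancreatic acinus and squamous epithelium lists, with 0 tested genes each, and the interstitial cells of Cajal, with 1. Lists were tested with camera of limma with the preset correlation of 0.01 and with a correlation estimated from the data, adjusted over the lists. A member counts as risen or fallen when its adjusted p over all tested genes was under 0.05, and counts adjusted over the list alone are given beside. Added later was a test of each patient's mean over a list, by 100000 random sign flips of the changes, or permutations of the diabetes labels. Measures of library make-up were tested by such sign flips too, adjusted over 6 measures.

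The genes named were fixed by a rule: protein-coding genes past the threshold with a mean of at least 1 FPKM in the higher group and the same direction in at least 0.75 of the patients, the 12 with the largest rise and the 12 with the largest fall in all patients, and the 8 largest in each direction for other comparisons. Where none passed, the 3 with the smallest p are named. For each list, up to 4 members of largest change among those that passed are named, or up to 2 where none passed. Some genes that met this rule are not reported here. Immunoglobulin and T cell receptor segments and classical HLA genes are not named. Genes of the glucocorticoid and brush border lists were chosen later, for the closing section.

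Alternatives, with effects in the closing section, were no patient block, patient as a random effect, a pseudocount of 0.1, no filter or a filter at 2 FPKM, rescaling by the median of ratios, quantile normalization, array weights, voom on the recovered fragments, a Wilcoxon test, and the mean of the smooth muscle or of the enterocyte markers as a covariate. Added after the data were seen were runs without the patient with the shallowest library, without the 5 patients with a library of at least 20% mitochondrial fragments, and with the mitochondrial share as a covariate. Whether diabetes went into remission, and clinical measurements, were not analysed here.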

Results

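Gene expression was measured by sequencing of poly-A RNA in samples of the human jejunum, from the segment that becomes the Roux limb in Roux-en-Y gastric bypass, an operation that reduces the stomach to a small pouch and joins it to the jejunum. Each of 28 patients gave a sample before surgery, called baseline here, and a sample 12 months after it, which made 56 libraries. Diabetes was recorded for 15 of the patients and its absence for 13, so the 4 groups held 15, 13, 15 and 13 libraries. The libraries held 8.43 to 22.2 M fragments assigned to genes, with a median of 15.7 M. A count of 3 fragments on a gene of 1 kb, taken as the floor of detection, stood for 0.128 to 0.403 FPKM, a limit that covers counting error only. Values are means in FPKM ± SD, and changes are log2 changes of FPKM + 1 ± SE, 12 months minus baseline, with gene positions on GRCh38.

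The first comparison asked how jejunal expression differed 12 months after surgery from baseline in all 28 patients. In fixed gene lists, 10 of 19 genes of fat oxidation and 9 of 19 of fat absorption were lower at 12 months, and 20 of 22 of cholesterol synthesis, 25 of 31 of the cell cycle and 7 of 13 of epithelial defence were higher. With a correlation between list members estimated from the data, 0 of 59 lists passed, and the lowest adjusted p was 0.262. Of the cell type markers, 8 of 9 for plasma cells and 8 of 10 for B cells rose, whereas 7 of 9 for macrophages, 10 of 11 for T cells and 11 of 12 for fibroblasts fell (adjusted p = 0.362 to 0.518 for these lists with that estimate). The mean of the enterocyte markers was lower in 25 of 28 patients. With that mean as a covariate, the cell cycle median turned to -0.15. Epithelial defence, plasma cell and B cell lists then did not pass camera (adjusted p = 0.357, 0.507 and 0.305). APOA1, the main protein of HDL, dropped from 7958 ± 4390 to 2025 ± 1533 FPKM, a log2 change of -2.29 ± 0.25 that went down in 28 of 28 patients. PIGR, the receptor that carries IgA across the epithelium, climbed from 1057 ± 235 to 2774 ± 1022 FPKM, by 1.34 ± 0.11, and was higher in 28 of 28 patients.

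Of 17293 tested genes, 7679 changed in the test of all patients (limma, adjusted p under 0.05), 3848 upward and 3831 downward. A change of at least 1 on the log2 scale was seen in 181 of them, 48 higher and 133 lower. Against the other rises stood LCN2, which encodes the iron-scavenging defence protein lipocalin (chromosome 9, 128149071 to 128153455), at 1.63 ± 2.28 FPKM before and 12.1 ± 13.2 after surgery, a change of 2.09 ± 0.24. CPO, a brush border carboxypeptidase, rose from 1.61 to 12.5 FPKM, and ALDOC, an aldolase of glycolysis, from 9.80 to 33.3 FPKM. IRF4, a transcription factor of plasma cells and activated lymphocytes, went from 2.99 ± 1.85 to 9.75 ± 4.51 FPKM and was higher in 28 of 28 patients. TSPAN1 increased by 1.46, the regenerating protein gene REG1B by 1.78, CDC42EP5 by 1.23, the macrophage elastase gene MMP12 by 1.19, GP2 by 1.15 and the glutathione peroxidase gene GPX2 by 1.12. The kinase gene PNCK rose from 0.325 to 3.36 FPKM. The call for REG1B was lost with a smooth muscle score as a covariate (1.19, adjusted p = 0.0543), and that for GPX2 with an enterocyte score as a covariate (0.28, adjusted p = 0.381).

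Among the falls, PDK4, a kinase that shuts off pyruvate dehydrogenase and spares glucose (chromosome 7, 95583499 to 95596491), went from 169 ± 116 to 20.1 ± 9.97 FPKM, by -2.76 ± 0.22, in 28 of 28 patients. GIMD1 had the smallest adjusted p, 2.1e-16, with 16.2 ± 6.37 FPKM at baseline and 2.18 ± 1.22 FPKM at 12 months. The haemoglobin genes HBB and HBA2 changed by -3.29 and -2.93, LYPD8, which encodes an epithelial protein that binds gut bacteria, by -2.39, and SLC22A17 by -2.23. SGK1 and TSC22D3, both known to be induced by glucocorticoids, changed by -2.32 and -1.91. CYP1A1, a classical target of the aryl hydrocarbon receptor, changed by -2.01, and lactase (LCT) by -1.89, from 662 to 235 FPKM.

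**Figure D1:**
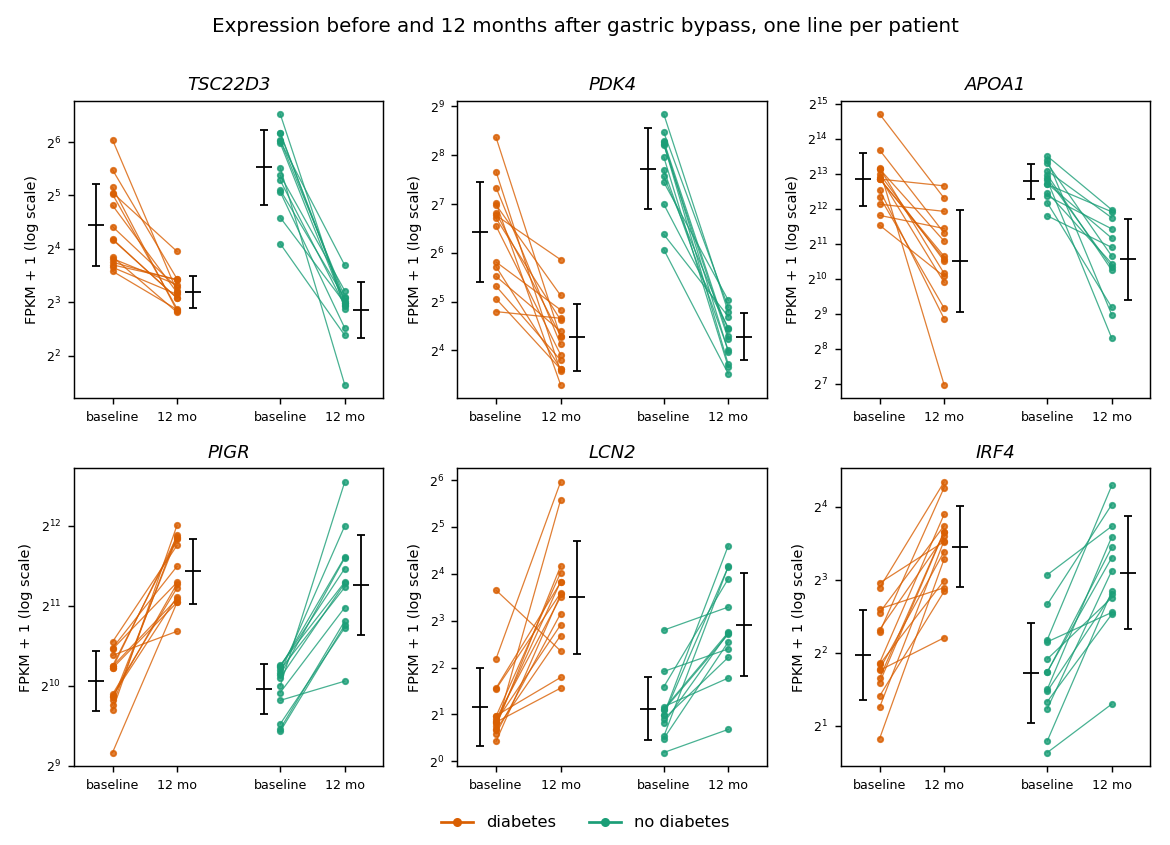
FPKM + 1 on a log2 axis for 6 genes at baseline and at 12 months, with 1 line per patient, 15 patients with diabetes and 13 without, and black bars for the mean and SD of the log2 values in each group. TSC22D3, PDK4 and APOA1 were lower and PIGR and IRF4 higher at 12 months in 28 of 28 patients, and LCN2 was higher in 27 of 28.

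Of the 59 fixed gene lists that had enough tested genes, 34 passed camera with its preset correlation, 13 upward and 21 downward, and 0 passed with a correlation estimated from the data, where the lowest adjusted p was 0.262. In a permutation test of each patient's list mean, added after these results were seen, 43 lists passed, 13 upward and 30 downward. Of the 34, all but oxidative phosphorylation, that is 33, passed this test in the same direction. The permutation test sets a list mean against 0 and not against other genes. As 7679 of 17293 genes changed, passing it does not show that a list changed more than other genes. Counts of members adjusted over the list alone follow each list's count.

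Fat and fuel metabolism moved in opposite directions by pathway. In the list of fatty acid oxidation and ketogenesis, 10 of 19 genes fell and 1 rose, or 11 and 2 adjusted over the list alone (adjusted p = 0.000285, and adjusted p = 0.392 with an estimated correlation). PDK4 was among them, as were the acyl-CoA enzymes ACADM (34.7 to 20.6 FPKM) and ACAA2 (46.1 to 28.3 FPKM). In lipid absorption and chylomicron assembly, 9 of 19 fell and 0 rose, also 9 and 0 adjusted over the list alone (adjusted p = 0.000343, and adjusted p = 0.518 with an estimated correlation). The chylomicron protein gene APOA4 went from 6495 to 1942 FPKM, APOC3 from 2120 to 620.2 FPKM, DGAT2, which makes triglyceride, from 13.8 to 2.94 FPKM, and the lipid droplet gene PLIN2 from 78.0 to 31.4 FPKM. Cholesterol synthesis rose in 20 of 22 genes, and in 22 of 22 adjusted over the list alone (adjusted p = 1.47e-09, and adjusted p = 0.362 with an estimated correlation). INSIG1, which restrains this pathway, rose from 17.1 to 32.2 FPKM, MSMO1 from 26.6 to 46.0 FPKM and IDI1 from 11.05 to 18.8 FPKM. The list mean was higher in 25 of 28 patients. Glycolysis rose in 10 of 15 genes and fell in 1, with equal counts adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.362 with an estimated correlation). They included ENO1 (92.1 to 130.1 FPKM) and GAPDH (289.6 to 394 FPKM). Insulin signalling fell in 11 of 16 genes and rose in 1, with equal counts adjusted over the list alone (adjusted p = 0.000383, and adjusted p = 0.262 with an estimated correlation). Its largest falls were in IGFBP3 and IGFBP5, which bind insulin-like growth factors (-1.29 and -0.72), and in the signal carriers IRS2 (-0.71) and PIK3R1 (-0.60). The call for IGFBP5 was lost with the smooth muscle score (-0.16, adjusted p = 0.601) and with the mitochondrial share as a covariate (-0.45, adjusted p = 0.0504). GAPDH lost its call with the smooth muscle score (0.28, adjusted p = 0.0815) and with the enterocyte score (0.32, adjusted p = 0.0607). With the mean of the enterocyte markers as a covariate, the median was -0.03 for fatty acid oxidation (adjusted p = 0.273) and turned to 0.26 for lipid absorption (adjusted p = 0.103), which shares genes with those markers.

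Absorptive and detoxifying genes of the epithelium fell in part. The enterocyte markers fell in 10 of 16 genes and rose in 1, with equal counts adjusted over the list alone (adjusted p = 4.78e-05, and adjusted p = 0.386 with an estimated correlation). Their mean was lower in 25 of 28 patients, and the list shares 6 of its 16 genes with the lipid absorption list and 4 with the carbohydrate list. Xenobiotic metabolism fell in 8 of 18 genes and rose in 2, or 9 and 2 adjusted over the list alone (adjusted p = 0.0304, and adjusted p = 0.588 with an estimated correlation). The drug-metabolising CYP3A4 fell from 534 to 269 FPKM, and the glutathione transferase GSTA1 rose from 361 to 694 FPKM. Targets of the aryl hydrocarbon receptor fell in 5 of 6 genes and rose in 1, NQO1, with equal counts adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.362 with an estimated correlation). Of 15 circadian clock genes, 9 fell and 1 rose, with equal counts adjusted over the list alone (adjusted p = 0.00891, and adjusted p = 0.362 with an estimated correlation). PER1 fell most (13.7 to 3.58 FPKM) and then the nuclear receptor gene NR1D1 (13.96 to 5.80 FPKM). Sampling hours are not given in the sources used here. Immediate early genes, which respond within minutes to growth signals and to handling, fell in 8 of 16 and rose in 2, with equal counts adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.533 with an estimated correlation). EGR1 stood at 15.1 and 3.13 FPKM. The enterocyte score as a covariate turned xenobiotic metabolism upward (median 0.32, adjusted p = 0.00967) and ended the calls for aryl hydrocarbon receptor targets and the clock (medians -0.27 and -0.34 against -0.34 and -0.44, adjusted p = 0.121 and 0.242). The smooth muscle score ended those for aryl hydrocarbon receptor targets and immediate early genes (medians -0.12 and -0.19 against -0.34 and -0.43, adjusted p = 0.130 and 0.393). Of the single genes, CYP3A4 lost its call with the enterocyte score (-0.35, adjusted p = 0.361), EGR1 with the smooth muscle score (-0.46, adjusted p = 0.254) and NR1D1 with each (-0.86, adjusted p = 0.0626, and -0.84, adjusted p = 0.0587).

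Genes of proliferation, secretion and defence rose. In the cell cycle list, 25 of 31 genes rose and 1 fell, or 26 and 1 adjusted over the list alone (adjusted p = 1.2e-06, and adjusted p = 0.518 with an estimated correlation). UBE2C stood at 5.83 FPKM before and 12.5 FPKM after surgery, and the kinase gene AURKB at 3.34 and 6.78 FPKM. The antimicrobial list rose in 7 of 13 genes and fell in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00193, and adjusted p = 0.362 with an estimated correlation). REG1A went from 688 to 1555 FPKM. Markers of crypt stem cells rose in 5 of 8 genes, also 5 adjusted over the list alone (adjusted p = 0.0304, and adjusted p = 0.545 with an estimated correlation). OLFM4 stood at 431 and 747 FPKM (0.70), but its call was lost without the patient term (0.70, adjusted p = 0.0753), with the patient as a random effect (0.70, adjusted p = 0.0672), without the filter (0.70, adjusted p = 0.0883), with quantile normalization (0.55, adjusted p = 0.104) and with voom (0.69, adjusted p = 0.0595), and it turned to -0.62 with the enterocyte score. Goblet cell markers, of the mucus-secreting cells, rose in 5 of 9, also 5 adjusted over the list alone (adjusted p = 0.0304, and adjusted p = 0.545 with an estimated correlation). AGR2 stood at 52.9 and 131 FPKM and the mucin gene MUC2 at 21.5 and 42.1 FPKM. Without the patient whose 12-month library was the shallowest, the crypt stem cell and goblet cell lists had adjusted p values of 0.0577 and 0.0752, with medians of 0.44 and 0.53 against 0.45 and 0.53 in all patients. The goblet cell call was also lost without the patient term (median 0.53, adjusted p = 0.0697). The unfolded protein list rose in 9 of 14 genes and fell in 1, or 10 and 1 adjusted over the list alone (adjusted p = 0.00929, and adjusted p = 0.362 with an estimated correlation). PDIA4, of the endoplasmic reticulum, stood at 39.1 and 58.3 FPKM. Heat shock genes rose in 5 of 11 and fell in 1, with equal counts adjusted over the list alone (adjusted p = 0.0434, and adjusted p = 0.545 with an estimated correlation). That call was lost after quantile normalization (median 0.13 against 0.17, adjusted p = 0.124), as was the goblet cell call (0.42 against 0.53, adjusted p = 0.0752). With the enterocyte score as a covariate, the medians of the cell cycle, crypt stem cell and goblet cell lists turned to -0.15, -0.19 and -0.10, and the calls for the antimicrobial, unfolded protein and heat shock lists were lost (medians 0.16, 0.11 and 0.054 against 0.81, 0.24 and 0.17, adjusted p = 0.357, 0.407 and 0.328). With that score UBE2C (0.15, adjusted p = 0.555), AURKB (0.23, adjusted p = 0.255), REG1A (0.10, adjusted p = 0.787), PDIA4 (0.15, adjusted p = 0.488), AGR2 (0.48, adjusted p = 0.0824) and MUC2 (0.46, adjusted p = 0.348) lost their calls, MUC2 also with the smooth muscle score (0.74, adjusted p = 0.102).

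Ribosomal protein genes rose, and fewer of the mitochondrial genes did, beside shifts in library make-up. Cytosolic ribosomal protein genes rose in 19 of 24, or 20 adjusted over the list alone (adjusted p = 4.78e-05, and adjusted p = 0.545 with an estimated correlation). RPL13 stood at 115 and 179 FPKM. Nuclear genes of oxidative phosphorylation rose in 7 of 24, or 4 adjusted over the list alone (adjusted p = 0.0302, and adjusted p = 0.671 with an estimated correlation). Quantile normalization, the smooth muscle score and the enterocyte score each ended this call (medians 0.10, 0.023 and 0.077 against 0.17, adjusted p = 0.207, 0.972 and 0.357), and the permutation test did not give it (adjusted p = 0.0885). The median of the ribosomal genes turned to -0.058 with the enterocyte score as a covariate, with which RPL13 lost its call (0.13, adjusted p = 0.581). The mitochondrially encoded transcripts rose in 4 of 13, also 4 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0477, and adjusted p = 0.636 with an estimated correlation), but their median was -0.02 after quantile normalization, under which MT-CO3 and MT-ATP6 turned downward. These 2 genes lost their calls with the smooth muscle score (0.34 and 0.32, adjusted p = 0.239 and 0.236), with the mitochondrial share as a covariate (0.16 and 0.011, adjusted p = 0.268 and 0.919) and without the filter on low values (0.46 and 0.36, adjusted p = 0.495 and 0.509). MT-ATP6 lost its call with a pseudocount of 0.1 (0.36, adjusted p = 0.0685) and without the 5 patients with a high mitochondrial share (0.15, adjusted p = 0.275) as well. The call for the list of mitochondrial transcripts was also lost, at about the same median, with the smooth muscle score as a covariate (0.26, adjusted p = 0.118), with a pseudocount of 0.1 (0.27, adjusted p = 0.0555) and without the patient with the shallowest library (0.26, adjusted p = 0.0865). The median was 0.043 and the adjusted p 0.617 without the 5 patients who had a library of at least 20% mitochondrial fragments. The mitochondrial share of fragments was 12.0% ± 1.80 at baseline and 15.2% ± 5.53 at 12 months, higher in 20 of 28 patients (permutation test, adjusted p = 0.00388). The 50 most abundant genes held 24.8% ± 2.29 and 28.2% ± 4.83 of the fragments (adjusted p = 0.0025), and the genes detected fell from 27553 ± 922 to 25950 ± 1939, in all but 3 patients (adjusted p = 0.0003).

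Immune markers separated by lineage. Plasma cell markers rose in 8 of 9 genes and fell in 1, with equal counts adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.362 with an estimated correlation). JCHAIN, which joins IgA and IgM into polymers, went from 1057 to 1886 FPKM and the plasma cell receptor gene TNFRSF17 from 5.58 to 10.6 FPKM, while PRDM1, a regulator of plasma cell identity that other cells also use, fell from 4.49 to 2.59 FPKM. Immunoglobulin genes held 1.40% ± 0.70 of the fragments at baseline and 2.40% ± 1.16 at 12 months, higher in 23 of 28 patients (permutation test, adjusted p = 0.0003). B cell and follicle markers rose in 8 of 10, also 8 adjusted over the list alone (adjusted p = 0.00384, and adjusted p = 0.518 with an estimated correlation). CD79A, a part of the B cell receptor, stood at 9.05 and 21.1 FPKM. Macrophage and monocyte markers fell in 7 of 9, also 7 adjusted over the list alone (adjusted p = 1.25e-05, and adjusted p = 0.362 with an estimated correlation). They included the complement genes C1QA (93.3 to 38.3 FPKM) and C1QB (64.5 to 28.3 FPKM) and the scavenger receptor gene CD163 (6.46 to 2.25 FPKM). T cell markers fell in 10 of 11, also 10 adjusted over the list alone (adjusted p = 2.12e-05, and adjusted p = 0.362 with an estimated correlation). IL7R stood at 15.8 and 6.05 FPKM and CD8A at 12.6 and 5.61 FPKM. Cytotoxic lymphocyte markers fell in 8 of 9, also 8 adjusted over the list alone (adjusted p = 1.56e-05, and adjusted p = 0.322 with an estimated correlation). Their mean was lower in 28 of 28 patients, and GZMA, a granule protease, stood at 25.8 and 10.9 FPKM. MHC class II presentation fell in 7 of 9, or 8 adjusted over the list alone (adjusted p = 1.04e-05, and adjusted p = 0.262 with an estimated correlation). CD74, the invariant chain, stood at 734 and 458 FPKM, and the list mean was lower in 28 of 28 patients. Interferon response genes fell in 9 of 20, also 9 adjusted over the list alone (adjusted p = 0.00649, and adjusted p = 0.533 with an estimated correlation). Mast cell markers fell in 5 of 6, also 5 adjusted over the list alone (adjusted p = 0.0477, and adjusted p = 0.545 with an estimated correlation). The plasma cell and B cell calls were lost with the enterocyte score as a covariate (medians 0.18 and 0.24, adjusted p = 0.507 and 0.305), as were those for JCHAIN (0.18, adjusted p = 0.605), TNFRSF17 (0.052, adjusted p = 0.866) and CD79A (0.31, adjusted p = 0.412). The mast cell call was lost without the patient term at the same median (-0.47, adjusted p = 0.0906), and with a pseudocount of 0.1 (-0.82, adjusted p = 0.0613).

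Connective tissue, vessel, muscle and blood markers fell. Fibroblast markers fell in 11 of 12, also 11 adjusted over the list alone (adjusted p = 3.06e-05, and adjusted p = 0.362 with an estimated correlation). ADAMDEC1, a gene of mucosal fibroblasts and macrophages, stood at 197 and 98.1 FPKM, and the collagen-binding decorin gene DCN at 11.2 and 5.16 FPKM. Extracellular matrix genes fell in 17 of 22 and rose in 3, with equal counts adjusted over the list alone (adjusted p = 4.78e-05, and adjusted p = 0.459 with an estimated correlation). The basement membrane collagen gene COL4A1 stood at 9.09 and 4.73 FPKM, and the collagenase gene MMP1 rose from 3.28 to 17.4 FPKM. Blood endothelium fell in 8 of 9, or 9 adjusted over the list alone (adjusted p = 0.000478, and adjusted p = 0.389 with an estimated correlation). Lymphatic endothelium fell in 4 of 5, also 4 adjusted over the list alone (adjusted p = 0.0215, and adjusted p = 0.421 with an estimated correlation). Smooth muscle fell in 13 of 14 genes, also 13 adjusted over the list alone (adjusted p = 1.04e-05, and adjusted p = 0.362 with an estimated correlation), and the myosin gene MYH11 stood at 20.2 and 11.7 FPKM. Enteric neuron markers fell in 3 of 3, also 3 adjusted over the list alone (adjusted p = 0.0245, and adjusted p = 0.362 with an estimated correlation). Haemoglobin genes fell in 3 of 3, also 3 adjusted over the list alone (adjusted p = 0.000106, and adjusted p = 0.262 with an estimated correlation). HBB went from 59.6 to 4.17 FPKM. With the mean of the smooth muscle markers as a covariate, 4039 genes changed instead of 7679, of which 3772 were among the 7679. With it the calls for blood endothelium, lymphatic endothelium, enteric neuron, extracellular matrix and mast cell lists were lost (medians -0.095, -0.10, -0.14, -0.29 and -0.15 against -0.40, -0.25, -0.41, -0.63 and -0.47, adjusted p = 0.283, 0.353, 0.249, 0.0527 and 0.787). Leaving out the 5 patients with a library of at least 20% mitochondrial fragments also ended the enteric neuron, lymphatic endothelium, mast cell and heat shock calls (medians -0.38, -0.13, -0.26 and 0.14 against -0.41, -0.25, -0.47 and 0.17, adjusted p = 0.0675, 0.0690, 0.212 and 0.0675).

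**Figure D2:**
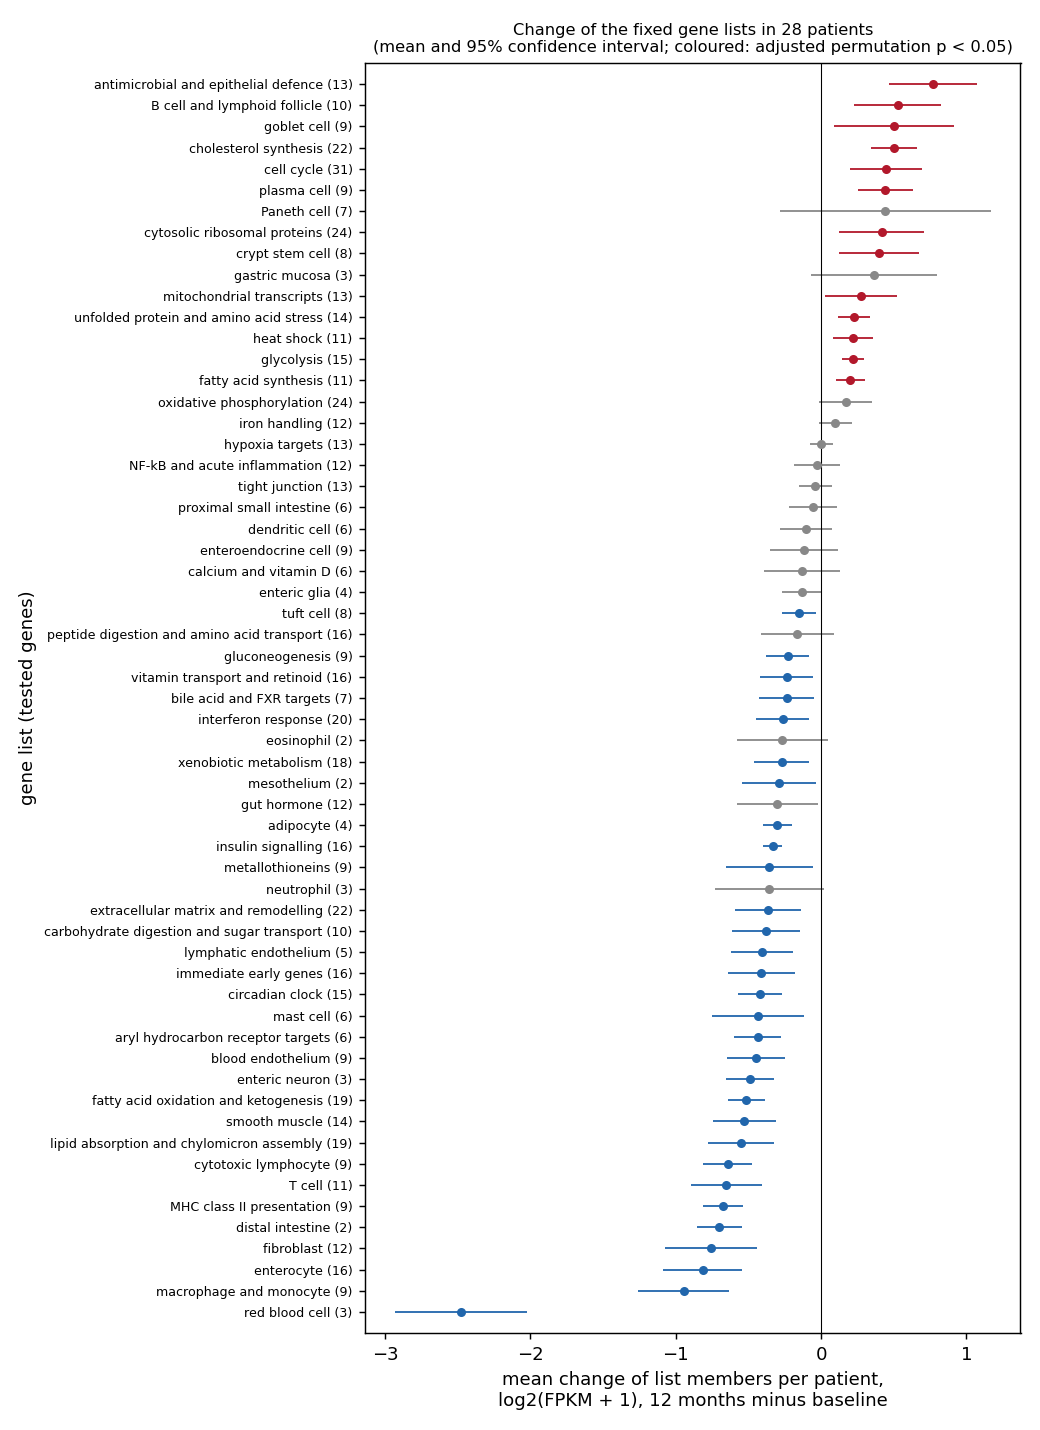
Mean change of the members of each of 59 fixed lists per patient, 12 months minus baseline in log2(FPKM + 1), with the 95% confidence interval over 28 patients, and the number of tested genes in parentheses. Red and blue mark the 13 lists that were higher and the 30 that were lower in the permutation test, grey the others, and the mitochondrial transcripts had a median of -0.02 after quantile normalization.

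The next comparison took the change within each patient group, as the title of the series concerns metabolic genes and the remission of diabetes. In the 15 patients with diabetes, APOA1 changed by -2.34 ± 0.35 and LYPD8 by -2.69 ± 0.25, and LCN2 rose by 2.34 ± 0.32. In the 13 patients without diabetes, PDK4 changed by -3.44 ± 0.28, SGK1 by -2.82 ± 0.26 and TSC22D3 by -2.67 ± 0.20, while MMP1 rose by 1.75 ± 0.50 and RNF186, a ubiquitin ligase gene of the gut epithelium, by 1.55 ± 0.23, from 28.3 to 80.3 FPKM. Cholesterol synthesis rose in 17 of 22 genes with diabetes and in 16 of 22 without, and 19 and 18 adjusted over the list alone (adjusted p = 0.364 and 0.402 with an estimated correlation). MHC class II presentation fell in 7 of 9 and 6 of 9 genes, with equal counts adjusted over the list alone (adjusted p = 0.364 and 0.316 with an estimated correlation).

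Of the 17293 genes, 4429 changed in patients with diabetes, 2050 upward and 2379 downward, and 4112 in patients without, 1770 upward and 2342 downward (limma, adjusted p under 0.05). Both groups shared 1125 genes that rose, where independent calls would share 209.8, and 1725 that fell, against 322. Called in opposite directions were 0 genes. Both tests used the same estimate of the spread of each gene, which can raise the overlap, so these counts are a description. Across the tested genes, which are not independent replicates, the changes of the groups had Pearson's r of 0.844 and Spearman's rho of 0.818, and 83.0% had the same sign. In patients with diabetes the other leading genes were REG1B (2.23), CPO (2.14), ALDOC (1.64), TSPAN1 (1.51), IRF4 (1.48), CDC42EP5 (1.39) and PIGR (1.37) upward and HBB (-2.78), GIMD1 (-2.60), HBA2 (-2.56), SLC22A17 (-2.17) and PDK4 (-2.16) downward. Without diabetes they were LCN2 (1.80), ALDOC (1.5), TSPAN1 (1.40), CPO (1.38), IRF4 (1.38) and PNCK (1.35) upward and HBB (-3.88), HBA2 (-3.36), SLC22A17 (-2.31) and GIMD1 (-2.28) downward. A smooth muscle score as a covariate left 2018 genes with diabetes, where the call for REG1B was lost (1.63, adjusted p = 0.0578), and 2424 without. Array weights gave 7050 genes with diabetes, and the Wilcoxon test gave 2186 without, where the call for MMP1 was lost at the same change (1.75, adjusted p = 0.0872). The excess of falls without diabetes depended on the fit. Leaving out the patient with the shallowest library gave 2785 genes upward and 2788 downward there, and array weights gave 2900 and 2937.

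**Figure D3:**
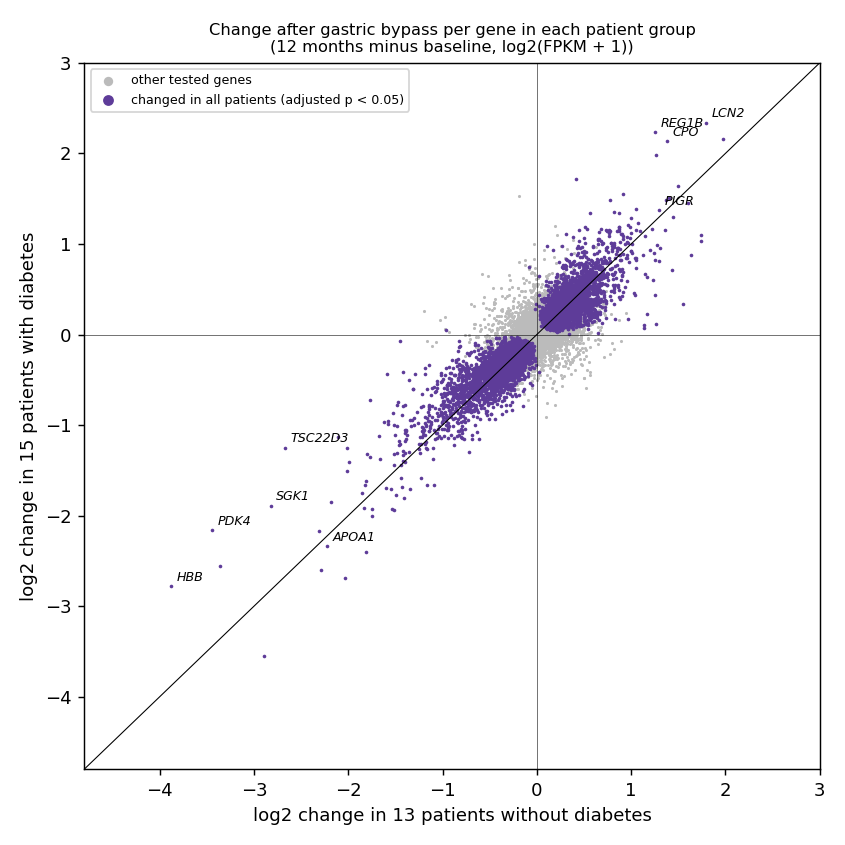
Log2 change after surgery for each of 17293 genes in 13 patients without diabetes (horizontal axis) and 15 patients with diabetes (vertical axis), with the line of equal change. Purple points are the 7679 genes that changed in all patients, and Pearson's r over all points was 0.844.

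The difference of the change by diabetes was then tested directly. TSC22D3 had the smallest p: its level went from 24.1 to 8.36 FPKM with diabetes and from 50.1 to 6.67 FPKM without, a difference in log2 change of 1.42 ± 0.28 that missed the threshold (adjusted p = 0.295). The next were TP53INP1, a target of p53 (0.54 ± 0.11, adjusted p = 0.327), and CCDC170 (-0.49 ± 0.12, adjusted p = 0.950). With limma 0 of 17293 genes passed, and 412 had an unadjusted p under 0.05. Voom on the recovered fragments and the Wilcoxon test also gave 0, with 406 and 450 at that unadjusted level. Camera with the preset correlation called 13 lists, 6 with a positive and 7 with a negative difference. Lipid absorption had 0 of 19 members past the threshold, also 0 adjusted over the list alone, and a median difference of -0.22 (adjusted p = 0.00131, and adjusted p = 0.778 with an estimated correlation). B cell markers had 0 of 10, also 0 adjusted over the list alone, and a median difference of -0.36 (adjusted p = 0.00131, and adjusted p = 0.778 with an estimated correlation). The 15 against 13 patients recovered 62% of 2-fold and 30% of 1.5-fold differences simulated for independent genes, so smaller differences were mostly not detectable.

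At baseline, patients with and without diabetes were compared to ask which genes differed before surgery. EPB41L5, which encodes a protein of epithelial polarity (chromosome 2, 120013005 to 120179119), stood at 4.01 ± 0.23 FPKM with diabetes and 3.42 ± 0.24 FPKM without, a log2 difference of 0.18 ± 0.03 that missed the threshold (adjusted p = 0.220). It passed with the Wilcoxon test (adjusted p = 0.00647) and without the filter on low values (adjusted p = 0.0366). CEBPA, a transcription factor gene of metabolic tissues, stood at 16.2 and 10.7 FPKM (0.54 ± 0.12, adjusted p = 0.323) and TP53INP1 at 9.42 and 12.7 FPKM (-0.40 ± 0.09, adjusted p = 0.323). With limma 0 of 17293 genes passed, with 1168 at an unadjusted p under 0.05, voom gave 0 with 1143, and the Wilcoxon test gave 1, EPB41L5, with 1234. Camera with the preset correlation called 18 lists, 8 higher and 10 lower with diabetes. Cholesterol synthesis had 0 of 22 genes past the threshold, also 0 adjusted over the list alone, and a median of 0.20 (adjusted p = 9.64e-07, and adjusted p = 0.486 with an estimated correlation). T cell markers had 0 of 11 past it, or 1 lower adjusted over the list alone, and a median of -0.20 (adjusted p = 5.37e-05, and adjusted p = 0.455 with an estimated correlation). Permuting the diabetes labels over the list means, added after these results were seen, gave 0 lists, with a lowest adjusted p of 0.131.

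At 12 months the same groups were compared to ask what still differed after surgery. The smallest p values were those of FAM25C (5.23 FPKM with diabetes and 0.803 FPKM without, 1.35 ± 0.38), the DNA repair protease gene SPRTN (1.30 and 1.005 FPKM, 0.20 ± 0.06) and MRI1, an enzyme of methionine salvage (5.47 and 7.02 FPKM, -0.33 ± 0.11), and none passed (adjusted p = 0.99986 for each). With limma 0 of 17293 genes passed, with 275 at an unadjusted p under 0.05, and voom and the Wilcoxon test gave 0, with 270 and 296. Camera with the preset correlation called 10 lists, 5 higher and 5 lower with diabetes. Cholesterol synthesis had 0 of 22 genes past the threshold, also 0 adjusted over the list alone, and a median difference of 0.18 (adjusted p = 2.18e-09, and adjusted p = 0.951 with an estimated correlation). B cell markers had 0 of 10, also 0 adjusted over the list alone, and a median of -0.43 (adjusted p = 1.85e-05, and adjusted p = 0.951 with an estimated correlation). Permuting the diabetes labels gave 0 lists, with a lowest adjusted p of 0.982.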

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

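Of the tests here, the permutation of the diabetes labels over list means was chosen after the list results had been seen. The change after surgery differed between patients with and without diabetes in 13 fixed lists by camera with its preset correlation, but in 0 with an estimated correlation, where the adjusted p of each was 0.778, and in 0 by permutation of the labels, where the lowest adjusted p was 0.862. No single gene passed the test of that difference with limma, where 412 genes had an unadjusted p under 0.05, nor with voom (406) or the Wilcoxon test (450). Of 100 random divisions of the patients, the real one included, 100 gave at least as many genes as the real count of 0, which every division must, so this comparison decides nothing about chance. The highest of the others gave 280 against a median of 0, so a structure of the samples apart from diabetes stays possible and was not tested.

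The median difference in log2 change, diabetes minus no diabetes, was -0.22 for lipid absorption and chylomicron assembly. For the iron handling list it was -0.17, and for interferon response genes -0.12. The metallothioneins, small proteins that bind zinc and copper, differed by 0.49. Insulin signalling differed by 0.048 and cell cycle genes by 0.19. The mitochondrial transcripts, whose share of fragments also varied with library make-up, differed by -0.19. Paneth cell markers differed by 0.72, the B cell and follicle markers by -0.36, and neutrophil markers by 0.66, for 3 tested genes. Smooth muscle differed by -0.16, red blood cell genes by 0.80 and genes of the proximal small intestine by -0.17.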

How the results depend on the processing

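Leaving out the patient with the shallowest library, leaving out the 5 patients with a library of at least 20% mitochondrial fragments, the mitochondrial share as a covariate, and the permutation tests on list means were added after the data had been seen. The count of changed genes stayed within 1.5 times of 7679 in all runs but 1, at 5460 to 9397, and the correlation of the changes between the patient groups ran from 0.763 to 0.882. A similar count does not mean the same genes. With the enterocyte score as a covariate 6030 genes were called, but only 3830 of the 7679 were still called. Of the 7679, 6663 kept their direction with that score. Without the replicate block, that is without the patient term, 7425, 4202 and 3867 genes changed in all patients, with diabetes and without, against 7679, 4429 and 4112. Depth put the floor of detection for a gene of 1 kb at 0.128 to 0.403 FPKM. In simulated data the test of all 28 patients recovered 64% of 1.5-fold and 94% of 2-fold changes with 4 false calls among 17093 unchanged genes, and the test of the 13 without diabetes 46% and 70%. These rates hold for independent genes. Random divisions of the real libraries called up to 41 genes without diabetes, with a median of 0. The median change of all genes stayed under 0.1 on the log2 scale under each scaling, and the size factors of the rescaling ran from 0.978 to 1.02. The Wilcoxon p values first came from the normal approximation, which called no gene in patients without diabetes. After that count had been seen they were made exact where a gene had no ties.

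The smooth muscle score as a covariate left 4039 genes in all patients, 2018 with diabetes and 2424 without. Array weights gave 7050 with diabetes, and the Wilcoxon test 2186 without. At baseline, 1 gene (EPB41L5) passed without the filter on low values and 1, again EPB41L5, with the Wilcoxon test. For these counts the cause was not tested. An estimated correlation in camera gave 0 lists after surgery against 34. By diabetes it gave 0, 0 and 0 lists for the change, baseline and 12 months, and so did the permutation of the labels (0, 0 and 0), against 13, 18 and 10. Both allow for the correlation between the genes of a list, which was estimated above the preset value of 0.01 in most lists. Whether that correlation accounts for the lost calls was not tested. The sign flips after surgery allow for it too and gave 43 lists, but they set a list mean against 0 and not against other genes.

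Turned directions came mostly from covariates. With the enterocyte score, which takes up any change shared with the 16 marker genes, the list medians turned to 0.32 for carbohydrate digestion, 0.57 for peptide digestion, 0.26 for lipid absorption, 0.21 for gluconeogenesis, 0.31 for iron, 0.39 for vitamin transport, 0.32 for xenobiotic metabolism, 0.20 for tight junction, 0.027 for enterocyte, 0.10 for mesothelium and 0.34 for proximal small intestine genes. For bile acid (0.37) and calcium and vitamin D (0.56) only the direction of camera turned, since their medians were above 0 before. They turned to -0.15 for cell cycle, -0.058 for ribosomal, -0.10 for goblet cell, -1.03 for Paneth cell and -0.19 for crypt stem cell genes. Single genes turned to 0.32 (SLC2A5), 0.27 (MEP1B), 0.14 (SLC1A1), 0.24 (ENPEP), 0.30 (SLC36A1) and 0.015 (TM4SF5), and to -0.11 (HSPD1), -0.036 (PSAT1), -0.064 (RPS2), -0.24 (SPINK4), -0.77 (PRSS2), -0.80 (REG3A), -0.18 (FEV), -0.62 (OLFM4), -0.046 (CDCA7), -0.039 (ASCL2) and -0.31 (SMOC2). The cause was not tested.

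With the smooth muscle score, lists turned to 0.23 (NF-kB), -0.038 (hypoxia), 0.092 (enteroendocrine cell), 0.082 (enteric glia) and 0.11 (dendritic cell), and genes to 0.077 (MYH11), 0.028 (CNN1) and 0.0070 (ACTG2), which are part of that score, and to 0.071 (S100B) and 0.14 (PLIN4). Quantile normalization turned mitochondrial transcripts to -0.021, MT-CO3 to -0.12 and MT-ATP6 to -0.070. Without the 5 patients with a high mitochondrial share, hypoxia targets turned to -0.0073 and enteroendocrine cell markers to 0.094. In the permutation test of list means over all 28 patients, the iron list mean was 0.098 against a downward camera result. The cause was not tested. Of 3059 values for 206 changed named genes under the alternatives, 2829 kept direction and call, 209 kept direction and lost the call, and 21 turned.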

Other observations

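The permutation tests of list means, the dilution test, the fasting test, the comparisons that use all members of the 2 fat lists and the fits that leave out patients or use the mitochondrial share were chosen after the results they concern had been seen. Several nutrient lists did not pass camera yet held genes with large changes. Carbohydrate digestion and sugar transport fell in 5 of 10 genes and rose in 1 (adjusted p = 0.132), with trehalase (TREH) at 75.2 FPKM before and 39.7 FPKM after surgery. Peptide digestion and amino acid transport fell in 5 of 16 and rose in 2 (adjusted p = 0.179), led by the brush border protease gene MEP1B (-0.62 ± 0.15). Fatty acid synthesis rose in 6 of 11 and fell in 2 (adjusted p = 0.0838), with the desaturase gene SCD at 23.1 and 47.2 FPKM and ACSS2, which activates acetate, higher in 28 of 28 patients. Gluconeogenesis fell in 2 of 9 and rose in 1 (adjusted p = 0.256), and PCK1, its committed enzyme, went from 332 to 109 FPKM. The vitamin list fell in 4 of 16 genes and rose in 1 (adjusted p = 0.186), and SLC19A1 went from 21.03 to 5.67 FPKM and SLC46A1 from 44.3 to 17.7 FPKM. In the iron list 3 of 12 rose and 2 fell (adjusted p = 0.891), with the transferrin receptor gene TFRC at 13.2 and 32.98 FPKM and the iron importer gene SLC11A2 at 4.83 and 10.5 FPKM, higher in 28 of 28 patients. The iron list had a median of -0.08 and a mean of 0.10 with a downward test, the bile acid list a median of 0.12 and a mean of -0.24 with a downward test (2 of 7 fell and 1 rose, adjusted p = 0.569), and the calcium and vitamin D list a median of 0.21 and a mean of -0.13 with a downward test (2 of 6 fell and 1 rose, adjusted p = 0.892). The bile acid importer gene SLC10A2 went from 6.49 to 1.86 FPKM. Gut hormone genes fell in 5 of 12, or 4 adjusted over the list alone (adjusted p = 0.0649), with the incretin gene GIP at 185 and 97.9 FPKM and neurotensin (NTS) at 13.4 and 8.11 FPKM. The call for TREH was lost with the enterocyte score (-0.13, adjusted p = 0.450), as was that for SLC46A1 (-0.27, adjusted p = 0.401), while MEP1B turned (0.27, adjusted p = 0.0370), and that for NTS was lost with the smooth muscle score (-0.47, adjusted p = 0.125). Camera called the carbohydrate and peptide lists downward with the smooth muscle score (adjusted p = 0.0352 and 0.0301), after quantile normalization (0.0456 and 0.0481) and without the 5 patients with a high mitochondrial share (0.0453 and 0.0252), but upward with the enterocyte score (medians 0.32 and 0.57, adjusted p = 0.0231 and 5.46e-07). It called gluconeogenesis downward with the smooth muscle score (adjusted p = 0.0121) and gut hormones downward with a pseudocount of 0.1 (0.0497) and with the enterocyte score (0.000179), with which fatty acid synthesis (0.0283) and iron (0.0104) passed upward. In the permutation test of list means, the lists for carbohydrate digestion (adjusted p = 0.00435), fatty acid synthesis (0.000787), gluconeogenesis (0.00603), vitamins (0.0185) and bile acid (0.0226) did pass. For the other lists of these paragraphs the counts adjusted over the list alone were equal, except for tight junction, where 0 rose.

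Among defence, stress and cell type lists, metallothioneins fell in 3 of 9 (adjusted p = 0.0594), tight junction genes in 2 of 13 with 1 that rose (adjusted p = 0.554), NF-kB and acute inflammation in 3 of 12 with 2 that rose (adjusted p = 0.891) and hypoxia targets in 2 of 13 with 5 that rose (adjusted p = 0.887). NFKBIA, an inhibitor of NF-kB, went from 56.2 to 26.0 FPKM and ADM, which encodes the vessel-widening peptide adrenomedullin, from 4.998 to 1.81 FPKM in 28 of 28 patients. Paneth cell markers had 0 of 7 past the threshold (limma and camera, adjusted p = 0.308). Their list passed upward without the 5 patients with a high mitochondrial share (median 0.96, adjusted p = 0.00515) and with the smooth muscle score as a covariate (0.92, adjusted p = 0.0301), and downward with the enterocyte score (-1.03, adjusted p = 0.0231). Tuft cell markers fell in 4 of 8 and rose in 1 (adjusted p = 0.0995), enteroendocrine cell markers fell in 2 of 9 and rose in 1 (adjusted p = 0.551), enteric glia had 0 of 4 past it (adjusted p = 0.308), and dendritic cell markers fell in 3 of 6 and rose in 2 (adjusted p = 0.597). Neutrophil markers fell in 1 of 3 (adjusted p = 0.210), eosinophil in 1 of 2 (adjusted p = 0.190), adipocyte in 2 of 4 (adjusted p = 0.0649), mesothelium in 1 of 2 with 1 that rose (adjusted p = 0.708), distal intestine in 1 of 2 (adjusted p = 0.139), proximal small intestine in 1 of 6 (adjusted p = 0.800) and gastric mucosa in 0 of 3 (adjusted p = 0.406). Metallothioneins passed downward with the smooth muscle score, the enterocyte score and quantile normalization (adjusted p = 0.0359, 0.0215 and 0.0364). With the enterocyte score, camera also called enteroendocrine cell (0.00106), tuft cell (0.0110), enteric glia (0.0268), neutrophil and eosinophil lists (0.0231 each) downward, and tight junction (0.0265) and proximal small intestine (0.0231) upward. The permutation test passed metallothioneins (adjusted p = 0.0298), tuft cell (0.0203), mesothelium (0.0397), and adipocyte and distal intestine (4.54e-05 each), all downward. Antigen receptor segments parted by lineage: of the immunoglobulin segments 74 of 109 variable and 11 of 12 constant ones rose and 0 fell, and of the T cell receptor segments 15 of 42 variable and 5 of 6 constant ones fell and 0 rose. Across all tested genes, which are not independent, the change had a Spearman's rho of -0.230 with gene length, with medians of 0.072 in the shortest and -0.076 in the longest of 5 length classes.

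The counts of genes that changed after surgery were compared with random divisions. For all patients, for those with diabetes and for those without, 1 of 100 divisions, the real one, gave as many genes as 7679, 4429 and 4112, and the highest of the others gave 1, 0 and 41, so chance is excluded there. These divisions cannot tell surgery from differences in sample collection or library preparation that went with time. For the comparisons by diabetes at baseline and at 12 months, the real count was 0 with limma, which every division reaches (100 of 100, with highest others of 3 and 1), so nothing about chance is decided there.

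The 19 genes of fat oxidation and fat absorption that were called as lower fell on average by -1.04 ± 0.49 (SD over 28 patients), and all 38 tested members of the 2 lists, called or not, by -0.53 ± 0.41. Fewer enterocytes as the whole cause were weighed with 12 epithelial genes listed as brush border structure, 1 of them in a fixed list. Their mean change was -0.12 (95% interval -0.304 to 0.0570). It lay 0.40 (0.270 to 0.523) above 0.5 times the fall of the 19 genes, the bound set beforehand. The 19 were picked by their fall, and it lay 0.14 (0.0195 to 0.265) above 0.5 times that of all 38. These values argue against fewer enterocytes as the whole cause only if the 12 genes follow mature enterocytes, which was not tested. That is doubtful for EPCAM (3.3e-05) and CDH17 (0.18), which are adhesion genes and not brush border genes. The bounds were not computed without them, so fewer enterocytes stay open. Of the 12, CDHR2 (-0.59), ESPN (-0.36) and PLS1 (-0.31) fell past the threshold and 0 rose. A part played by enterocytes stays open, since the enterocyte marker mean fell by -0.81, in 25 of 28 patients, and with that score as a covariate the median was -0.031 for fatty acid oxidation and 0.26 for lipid absorption, which shares 6 genes with the score. The mitochondrial share of the libraries as the whole cause was argued against. All 19 of 19 genes stayed past the threshold without the 5 patients with a high share and with that share as a covariate. RNA integrity and depth were not part of these fits, so RNA quality in a wider sense stays open. A glucocorticoid signal in the baseline samples stays open as a cause and was not tested directly. Diet, weight, medication, the site of the limb and differences in sample collection or library preparation between the time points stay open and untested too. The mean of 11 glucocorticoid targets not looked at before changed by -0.42 (-0.558 to -0.274, permutation p = 1e-05), with 8 of them lower and 1, MAOA, higher. That fall was predicted beforehand for such a signal, so the prediction was met, but it does not show that the signal lowered the fat genes. Whether a shift in cell types made part of the fall of the 11 targets was not tested. A further condition was added later, that the 38 fat genes be lower with diabetes at baseline, as the mean of the 11 targets was. They differed by 0.10 (-0.106 to 0.315), so that condition was not met and the question stays undecided.

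Macrophage, T cell and stromal markers fell while plasma and B cell markers rose. Shallower sampling with less muscle as the whole cause was argued against for macrophage, T cell and cytotoxic markers, since 19 of 25 stayed past the threshold with the smooth muscle score as a covariate, with a mean of -0.83 before and -0.70 after. That was the lowest count that met the bound set beforehand, and such a score may take up only part of a difference in depth. Shallower sampling stays open for fibroblast and endothelial markers, of which 5 of 23 stayed, with a mean and SD over genes of -0.65 ± 0.31 before and -0.33 ± 0.26 after, so these may follow the depth of the sample: the mean change shrank while the median SE went from 0.139 to 0.157, so smaller changes and lower precision both entered the lost calls. For dilution by a larger epithelial or plasma cell share, equal falls of these markers were predicted. The macrophage markers fell further than blood endothelium per patient, by -0.49 (-0.733 to -0.256, permutation p = 0.0002). Adding 1 to each FPKM shrinks the changes of genes with low values, however. Equal dilution can thus give unequal changes, so dilution stays open. The mitochondrial share as the whole cause was argued against by 66 of 73 markers staying in 1 fit and 70 in the other. RNA integrity and depth were not part of these fits. Haemoglobin genes also fell after surgery, by a mean of -2.48 over 3 genes, and were lower in 27 of 28 patients. Whether less blood in the samples made part of the falls of macrophage, T cell and cytotoxic markers was not tested, so that stays open. A change in the immune cells of the limb itself remains open as a hypothesis, which was not tested either.

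At baseline, 5 glucocorticoid-responsive genes picked after their values were seen (TSC22D3, PER1, SGK1, KLF9 and PDK4) were lower with diabetes than without, by -0.88 on average, a difference they were picked for, and none passed alone. The mean of the 11 targets not looked at before differed the same way, by -0.38 (-0.602 to -0.162, permutation p = 0.0007), and by 0.024 at 12 months (permutation p = 0.681). The baseline value lay below all of 10000 random lists. These were drawn gene by gene, without the correlation between the 11 genes, so that rank is only a description. None of the 11 passed alone, from FKBP5 (-1.24 ± 0.41, adjusted p = 0.576) to MERTK (-0.062) and CDKN1C (0.016). Cell types other than enterocytes were not tested as a source of this difference. For the 5 genes, a difference in enterocyte share was argued against. They differed by -0.88 without and by -1.005 (-1.54 to -0.470) with the enterocyte score as a covariate. As they were picked for a difference, only the lack of shrinkage counts, and the 11 targets were not fitted this way. A stronger fasting signal without diabetes was argued against only as far as 12 PPAR alpha targets carry it. These, 11 of them in fixed lists, differed by 0.11 (-0.0882 to 0.308). PDK4, of the fixed fat oxidation list, differed by -1.30 ± 0.34 but was counted with the 5 and not with the 12. A glucocorticoid signal that was stronger at baseline in patients without diabetes may account for the difference, as a hypothesis found and tested on the same libraries. A steroid given around the operation and the stress of surgery are possible sources that the labels used here do not record.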
